A study of Arabidopsis thaliana with 6 samples.

How the data were processed

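Whole-genome bisulfite sequencing was done on hand-dissected Arabidopsis thaliana endosperm from 3 crosses, with 2 labelled replicates each and 6 samples in all. Per the labels, the submitters used Trim Galore, FastQC and Bismark with the TAIR10 genome and gave no versions. The authors deposited 9 tables of window statistics, 1 per context and pair of crosses, and 18 lists of regions. The replicates of a cross are combined in all of them, and how they were combined is not stated.

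Per the file headers, each table gives counts of methylated cytosine calls in windows of 300 bp placed every 100 bp. Other columns, per the file headers, give unmethylated call counts and the number of cytosines with data in both crosses. The authors' methylation level is a percent, equal to methylated calls over all calls. The authors' score for a window is the difference in level in percentage points, the cross named second minus the cross named first. The p-value columns deposited by the authors hold the p value of Fisher's exact test per window and its Benjamini-Hochberg adjusted value. The other unit, in the authors' region lists, is the region length in bp. The lists state no thresholds. Tested on the files, the listed regions were windows with an adjusted p below 0.01 and a difference of at least 30 percentage points in CG, 20 in CHG and 10 in CHH, merged where they overlap.

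Comparisons were lethal against balanced, viable against balanced, and viable against lethal, each for CG, CHG and CHH and on the 5 nuclear chromosomes. The authors' regions were counted after merging. Fisher's exact test (two-sided) was recomputed for every window, with Benjamini-Hochberg adjustment, and windows with at least 10 calls in each cross were counted. The recomputed and deposited p differed by at most 2.17e-05 on the log10 scale, and 0 windows changed side. Weighted levels are summed methylated calls over summed calls in windows that do not overlap, genome-wide over every table that holds the cross and by bins over windows present in all 3 tables. Their 95% intervals are Wilson intervals. A level of 0 allows a share of up to 3 calls of the total. Reads give several calls each, so intervals, limits and window p values cover counting error only.

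Genes and symbols came from a gene table of the TAIR10.1 assembly with 37899 genes, of which 27444 are protein-coding. Its placement was checked on the CG level at the ends of genes of at least 3 kb, which was lowest at their ends. The table gives no strand, so 2 kb on both sides of a gene stood in for 2 kb upstream of it. Positions of transposable elements were not analysed here, and the table's pseudogene class was used. Bins of 500 kb were called gene-poor when their gene density lay below the chromosome median. Location was tested with Fisher's exact test on windows that do not overlap, against all tested windows. Overlap between contexts was set against 1000 random placements of tested windows.

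The 9 gene lists with 84 genes, the comparisons and the rule for named genes were fixed before the data were examined. The lists were paternally expressed genes, maternally expressed genes, type I MADS-box genes, the RdDM pathway, methylation maintenance and removal, PRC2, endosperm growth, embryo markers and seed coat markers. The rule names list members with a region in the gene or within 2 kb, the 3 protein-coding genes with a symbol and the largest absolute difference per comparison, context and direction, and the longest region of each. Values of a named gene come from its window of largest difference, and these windows held 6 to 2162 calls per cross.

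The test, without merging, was tried on simulated data. All windows were redrawn with counting error alone at their real numbers of calls, and 200 were changed by known amounts. Recovery with a wider spread was not simulated. In CHH, of 100 windows raised by the smaller amount, 77 were recovered for lethal against balanced, 74 for viable against balanced and 79 for viable against lethal. For CG the numbers were 51, 60 and 53. Unchanged lethal and viable crosses were also simulated against the shared balanced calls, with binomial draws and with the spread estimated from the windows. That spread is the median squared z over its expected value in windows with a level of 2% to 98% and at least 10 calls in each cross. Here z is the difference over its counting error, after the mean difference at each level was subtracted. The spread holds real differences too. Tests scaled to it were normal tests of the difference, without that subtraction, and not Fisher's exact tests.

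Alternatives were a stricter adjusted p, a stricter difference, no minimum difference, rebuilt regions, at least 6 shared cytosines, at least 20 calls, windows that do not overlap, unweighted levels, windows in all 3 tables, overlap of at least 50% of the shorter region, and 500 bp or 0 bp around genes. Tests scaled to the estimated spread, viable calls thinned to the lethal total, and levels with the chloroplast level subtracted, genome-wide and by bins, were added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 were used.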

Results

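DNA methylation was measured by whole-genome bisulfite sequencing in endosperm of Arabidopsis thaliana, the nutritive tissue of the seed, dissected by hand at 7 days after pollination. The mother was the Landsberg erecta accession (Ler) in all crosses. In the balanced cross the father was Columbia (Col). In the lethal paternal excess cross it was 4N Col, and in the viable paternal excess cross it was 4N Col carrying a mutation in NRPD1, which encodes the largest subunit of RNA polymerase IV in RNA-directed DNA methylation (RdDM). The labels name 2 replicates per cross, 6 samples in all, but the deposited tables hold 1 pooled set of calls per cross. Spread between replicates could therefore not be measured for any value below, and each Fisher's exact test (two-sided) compares pooled libraries, not conditions. The median 300 bp window held 97 CG calls in balanced, 91 in lethal and 127 in viable. For CHG it held 124, 118 and 164 calls, and for CHH 392, 373 and 523 calls, where H stands for any base but G.

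NRPD1 (AT1G63020), the gene mutated in the viable father, carried a CHG gain in the viable cross. A region inside the gene, at chromosome 1, 23355801 to 23357200 (TAIR10), was the longest CHG region gained in viable relative to balanced, at 1400 bp. In its window of largest difference the CHG level was 4.94% of 263 calls in balanced, 3.48% of 259 in lethal and 37.4% of 641 in viable. The adjusted p in the authors' deposited table was 2.90e-23 for viable against balanced and 3.12e-26 for viable against lethal. The methylation level of a gene does not show whether its mutant allele was present, so this value does not check the labels.

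CHH and CHG methylation were lower across the genome in both paternal excess crosses than in balanced, and genome-wide they were lowest in lethal. The weighted CHH level of the 5 nuclear chromosomes, the share of all calls that were methylated, was 6.84% in balanced, 4.38% in lethal and 4.96% in viable. The CHG level was 18.2% in balanced, 13.6% in lethal and 15.2% in viable. Lethal and viable lay closer together in the unweighted mean over windows, which was 4.25%, 2.58% and 2.92% in CHH and 10.3%, 8.21% and 8.31% in CHG, where viable minus lethal went from 1.57 to 0.102 percentage points. The CG level was 37.9% in balanced, 37.1% in lethal and 39.6% in viable, and here the order depended on the weighting: the mean over windows was 26.8%, 28.12% and 28.05%. In windows present in all 3 tables, the loss was large in gene-poor 500 kb bins, where CHH stood at 10.4%, 6.74% and 7.65% in balanced, lethal and viable, and CHG at 30%, 23.0% and 25.4%. In gene-rich bins CHH was 1.82%, 1.33% and 1.25% and CHG 3.34%, 2.70% and 2.61%, lowest in viable. That order turned with the conversion level: viable minus lethal was -0.079 percentage points in CHH and -0.09 in CHG, and 0.498 and 0.485 with the chloroplast level of each cross subtracted, an alternative chosen after seeing the data. The chloroplast genome, a measure of incomplete conversion, read 0.612% CHH in balanced, 1.04% in lethal and 0.466% in viable. No test was made of these levels, since each cross gave 1 pooled value, and the 95% Wilson interval, 6.83% to 6.84% for CHH in balanced, covers counting error only.

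**Figure D1:**
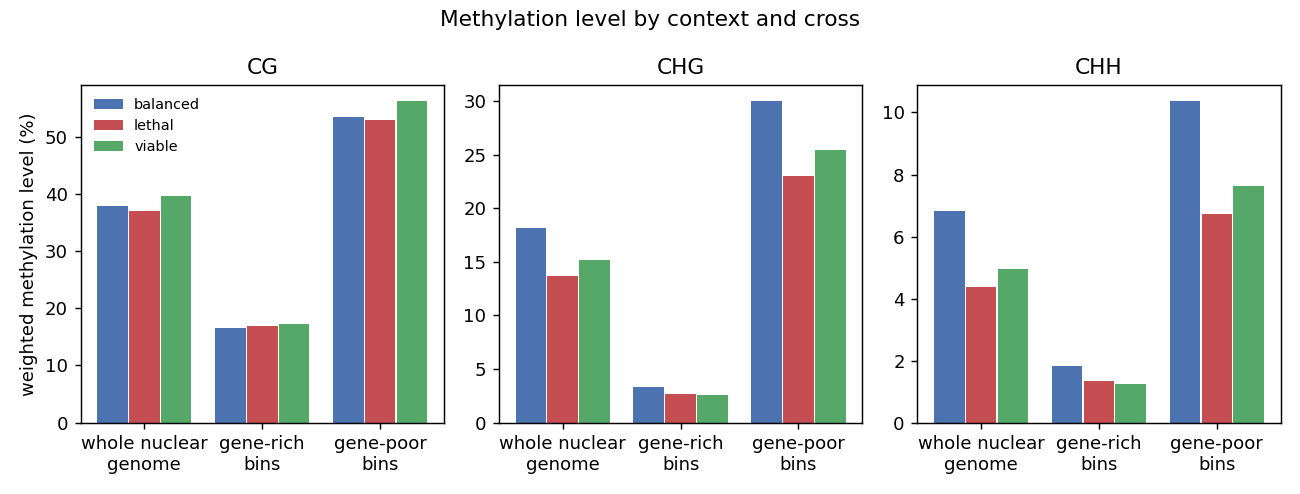
Weighted methylation level in percent (y axis) of the balanced, lethal and viable crosses in CG, CHG and CHH, for the whole nuclear genome (every table that holds the cross) and, in windows present in all 3 tables, for 121 gene-rich and 119 gene-poor bins of 500 kb (x axis); each bar is 1 pooled set of calls, so there is no error bar. In gene-poor bins the CHH bars stand at 10.4% in balanced, 6.74% in lethal and 7.65% in viable.

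The comparison of lethal with balanced asks what a 4N father does to endosperm methylation. CHH methylation fell in lethal at 11183 of the authors' regions, which cover 7233 kb, and rose at 336, or fell at 17968 and rose at 8171 without the minimum difference of 10 points. Incomplete conversion could add to the small rises, since the chloroplast CHH level was 1.04% in lethal and 0.612% in balanced. Its part in the 8171 was not tested. CHG fell at 4521 regions and rose at 19. CG went mostly the other way, with 1622 regions higher in lethal and 533 lower. In the regions of CHH loss the mean level was 24.5% ± 9.10 (SD over 11110 regions) in balanced and 6.74% ± 4.69 in lethal, and in those of CHG loss 54.2% ± 11.8 (4490 regions) and 27.5% ± 13.1. In the CG regions that rose it was 21.8% ± 17.2 (1596 regions) and 60.6% ± 17.9. The SD is a spread over regions, not over samples.

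CHH loss in lethal reached 31 of the 84 genes on the 9 lists fixed in advance, counting regions inside a gene or within 2 kb of it, and 30 of them when adjusted over the list alone. Counted in the same way, 22.5% of all measured protein-coding genes had CHH loss in lethal. Among the type I MADS-box genes, transcription factors active in endosperm, 10 of 19 measured members had such a region. AGL28 fell from 62.6% (454 calls) to 5.17% (116 calls), AGL62, a repressor of endosperm cellularisation, from 38.3% to 0% of 24 calls, which allows up to 12.5%, AGL80 from 39.3% to 0% and AGL36 from 28.4% to 7.41%. The regions of these values lay inside AGL28 and AGL62, and 1159 and 1189 bp beside AGL80 and AGL36. The other 6 genes were AGL23, AGL34, AGL40, AGL61, AGL91 and AGL92. AGL40, AGL46 and AGL80 also had a region of CHH gain, AGL46 from 0% of 54 calls to 15.6% of 160. Of 10 paternally expressed imprinted genes, 4 lost CHH: YUC10, an auxin biosynthesis gene, fell from 65.2% to 13.6%, SUVH7 from 26.1% to 3.79%, SUVH8 from 21.0% to 5.60% and ADM from 19.3% to 0%. The regions of these 4 values lay beside the gene, from 978 bp (SUVH7) to 1722 bp (YUC10) away. Of 6 maternally expressed genes, 2 did, AGL36 again and SDC, an F-box gene, which fell from 58.5% (284 calls) to 10.8% (157 calls) at chromosome 2, 7681401 to 7682400.

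The RdDM list had 6 of 17 members with CHH loss in lethal: SUVH9, which recruits RNA polymerase V, fell from 64.0% to 6.25%, CLSY1, which guides RNA polymerase IV, from 41.3% to 4.19% and DMS3 from 27.5% to 2.5%, with AGO4, DCL3 and RDR2. The regions of SUVH9 and CLSY1 lay 1893 and 1171 bp beside the gene. Those of AGO4, DCL3 and RDR2 also lay beside it, and that of DMS3 inside. Of 13 genes of methylation maintenance and removal, 4 had one. MET1, the CG maintenance methyltransferase, fell beside the gene from 47.8% (249 calls) to 3.50% (257 calls) at chromosome 5, 19930401 to 19930900. The demethylase genes DML2 and DML3 fell beside the gene from 55.2% to 7.35% and from 19.3% to 2.07%, and CMT2 inside it from 11.01% to 0.870%. Single members of other lists were SWN, a Polycomb methyltransferase gene (1 of 6 PRC2 genes, 41.7% to 2.17%), and SHB1 and AGL62 of 8 endosperm growth genes. Markers of other seed parts also lost CHH, all beside the gene: LEC1, FUS3 and STM of 5 embryo markers, and TT10 of 5 seed coat markers. FUS3 stood at 28.0% in balanced and 0% of 78 calls in lethal, which allows up to 3.85%.

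**Figure D2:**
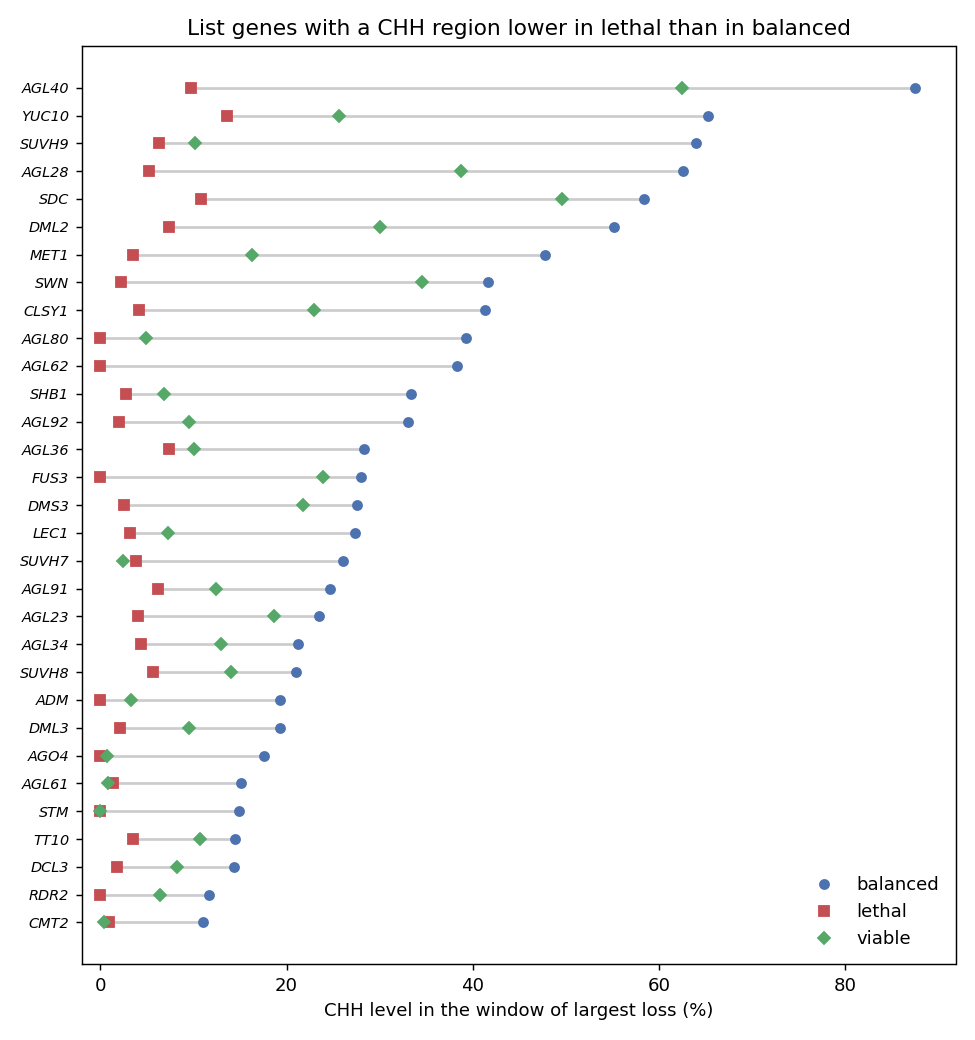
CHH level in percent (x axis) of the 31 list genes (y axis) with a CHH region lower in lethal than in balanced, in the window of largest loss; circles are balanced, squares lethal and diamonds viable, each from 1 pooled set of calls, and no viable value was given for AGL62. MET1 runs from 47.8% in balanced to 3.50% in lethal, with viable at 16.2%.

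CHG loss in lethal reached 9 list genes, 4 when adjusted over the list alone. These were AGL28, AGL36 and AGL92 of the MADS-box list, DML2, DML3 and MET1, and ADM, LEC1 and TT10; MET1 fell from 34.6% to 2.5%. In CG, the imprinted homeodomain gene FWA fell from 44.3% (70 calls) to 2.13% (47 calls) at chromosome 4, 13038101 to 13038500, and LEC1, beside the gene, from 53.6% to 14.3%. The Polycomb genes FIS2 and FIE rose in CG, from 1.59% to 40.3% at 1344 bp beside the gene and from 42.1% to 84.8% inside it. Adjusted over the list alone, the CG counts were also 2 lower and 2 higher. Among all measured protein-coding genes, 7.88% had a CHG loss in lethal in the gene or within 2 kb, 3.13% a CG loss and 9.39% a CG gain. Outside the lists, among protein-coding genes with a symbol, the largest CG falls lay beside ATA27 and SKP1, which share a region (95.1% to 0% of 29 calls), and bZIP42 (95.2% to 2.94%), and the largest CG rises beside LKP2 (0% to 100% of 9 calls), ENODL3 (0% to 95.2%) and in ECA3 (0% to 94.4%). The largest CHH falls lay at GPAT9 and PDIL1-4 (84.6% of 13 calls to 0%) and Tic20-IV (84.6% to 4.00%), and the largest CHH rises beside MEE48 (0.909% to 57.0%), EMB3111 (2.31% to 47.1%) and RPS15A (5.62% to 45%). For CHG the largest falls lay beside ATCSA-1 (85.7% to 8.33%), PAP15 (84.4% to 15.4%) and ARF4 (77.6% to 10.5%), and the largest rises at PHYC (0% to 45.7%) and at SHW1 and PPME1, which share a region (11.6% to 43.0%). Counted per gene, so that a shared region counts for each of its genes, 8 of these 18 calls passed with tests scaled to the estimated spread of the calls. They were those at ATA27 and SKP1 (the same region), ENODL3, ECA3, PAP15, ARF4, MEE48 and EMB3111.

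Calls spread more widely than counting error. The median squared difference for lethal against balanced was 2.55 (CG), 2.29 (CHG) and 6.14 (CHH) times its expected value. The mean difference at each level was subtracted first. With tests scaled to that spread, an alternative chosen after seeing the data, 1701 CHH and 981 CHG losses, 158 CG gains and 41 CG losses passed, and 5 of the 31 list genes with CHH loss had such a region: AGL28, AGL36, CLSY1, MET1 and SUVH9, as did 1 of the 9 with CHG loss (AGL92), 1 of 2 with CG gain (FIE), 0 of 2 with CG loss (FWA and LEC1) and 0 of 3 with CHH gain.

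**Figure D3:**
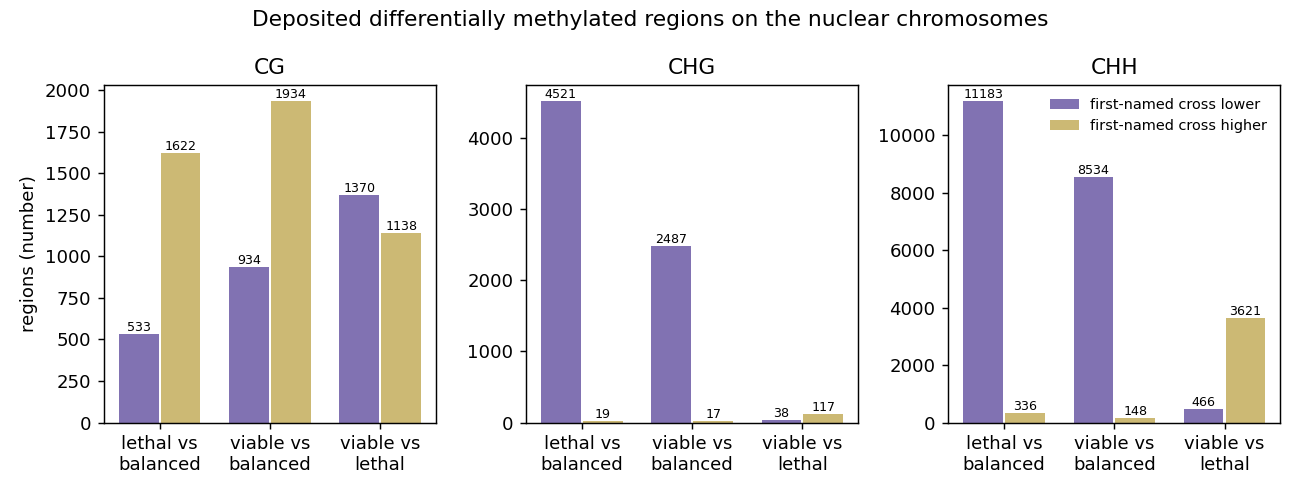
Number of the authors' differentially methylated regions on the nuclear chromosomes (y axis) for each pair of crosses (x axis) in CG, CHG and CHH; dark bars count regions in which the cross named first is lower, light bars those in which it is higher. CHH shows 11183 losses in lethal and 8534 in viable against balanced, and 3621 regions higher in viable than in lethal.

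The comparison of viable with balanced asks what the same paternal excess does when the father lacks NRPD1. CHH fell in viable at 8534 regions, which cover 4595 kb, and rose at 148, or fell at 19845 and rose at 678 without the minimum difference. CHG fell at 2487 regions and rose at 17, while CG rose at 1934 and fell at 934. The regions of CHH loss averaged 27.9% ± 10.6 (SD over 8247 regions) in balanced and 11.7% ± 7.56 in viable, those of CHG loss 53.3% ± 12.4 (2366 regions) and 27.5% ± 12.9, and the CG regions that rose 19.9% ± 16.6 (1847 regions) and 57.9% ± 17.0.

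CHH loss in viable reached 23 list genes, 22 when adjusted over the list alone, and 19.3% of all measured protein-coding genes. The type I MADS-box list had 8 of 19: AGL62 fell from 33.7% to 5.13% and AGL80 from 39.3% to 4.88%, and AGL28, AGL34, AGL36, AGL61, AGL91 and AGL92 also had a region. Among paternally expressed genes YUC10 fell from 65.2% to 25.7%, SUVH7 from 26.1% to 2.45% and ADM from 19.3% to 3.24%, 3 of 10. The regions of these 3 values lay beside the gene. SUVH9 (64.0% to 10.1%), CLSY1 (28.9% to 5.49%), AGO4 and RDR2 were the 4 RdDM members, with their regions of largest loss beside the gene. MET1 (43.7% to 11.8%), DML2, DML3 and CMT2 were the 4 of maintenance and removal. SHB1 (33.3% to 6.80%), the embryo markers LEC1 and STM, and the seed coat marker TT8 (17.8% to 4.91%) completed the set. No region of CHH loss in viable was listed at SDC, whose level was 49.6% of 262 calls against 58.5% in balanced.

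CHG loss in viable reached 7 list genes, 6 when adjusted over the list alone: SUVH7 (76.9% to 19.1%, beside the gene), YUC10 (86.7% to 30%) and PKR2 of the paternally expressed list, then AGL28, CKX2, DMS3 and MET1. CKX2, which encodes a cytokinin oxidase, fell beside the gene from 30.4% (168 calls) to 4.28% (257 calls). CG rose at 9 list genes, with VIM5 (2.94% to 51.1%), AGO6 (14.6% to 58.8%), DCL3 (40.4% to 72.8%), IBM1 (38.8% to 87.7%) and the demethylase gene DME (54.4% to 85.2%) besides FIS2, FIE, CKX2 and VIM1. It fell beside SUVH7 and SHB1 (91.8% to 46.4%), in KTF1 (84.5% to 34.2%) and at another region of VIM1. These CG counts, 9 and 4, were also reached when adjusted over the list alone. Among all measured protein-coding genes, 10.7% had a CG gain in viable in the gene or within 2 kb, 4.75% a CG loss and 5.90% a CHG loss. The largest CG falls outside the lists lay beside SQE6, SPT1 and chr31, each from 100% to 0% of 12 to 20 calls, and the largest rises beside EDA2 (0% to 100% of 17 calls), PHYC (0% of 8 calls to 97.7%) and in PMAT1 (0% to 84.6%). The largest CHH falls lay beside NIP2 (91.7% of 12 calls to 18.1%), NAC097 (73.3% to 0%) and MEE14 (80.0% to 7.69%), and the largest rises at EMB3111 (2.31% to 54.3%), MOS2 (0% to 44.2%) and PGDH (39.3% to 70.9%). In CHG, SRR1 and BOA shared a fall from 85.2% to 8.0%, ATCSA-1 fell to 13.0%, and RH8 and SCO1 rose beside the gene, to 46.7% and 38.4%. Counted per gene in the same way, 5 of these 17 calls passed with tests scaled to the estimated spread: those at SQE6, SPT1, PHYC, EMB3111 and MOS2.

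Median squared differences for viable against balanced were 2.71 (CG), 2.07 (CHG) and 3.95 (CHH) times their expected values. Scaled to that spread, 1701 CHH and 449 CHG losses, 285 CG gains and 129 CG losses passed. The CHH count equals that in lethal, but the tests were scaled by 3.95 in viable and 6.14 in lethal. Both factors hold real differences too, so equal counts do not show equal loss. A region that passed was left at 1 of 23 list genes with CHH loss (SUVH9), 1 of 7 with CHG loss (CKX2), 1 of 9 with CG gain (DCL3), 0 of 4 with CG loss, and at NRPD1.

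The comparison of viable with lethal asks what the paternal mutation changes at the same dosage. CHH was higher in viable at 3621 regions, which cover 1720 kb, and lower at 466, but without the minimum difference of 10 points 7686 regions were higher and 9737 lower. The chloroplast CHH level was 1.04% in lethal and 0.466% in viable, so incomplete conversion could add small CHH excesses in lethal. Its part in the 9737 was not tested. In the higher ones it averaged 31.4% ± 13.5 (SD over 3573 regions) in balanced, 5.39% ± 4.79 in lethal and 21.6% ± 8.33 in viable. CHG was higher in viable at 117 regions and lower at 38, with 52.6%, 16.5% and 43.8% in balanced, lethal and viable for the higher ones. CG differed in both directions, lower in viable at 1370 regions and higher at 1138.

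CHH was higher in viable than in lethal at 13 list genes, also 13 when adjusted over the list alone. SDC stood at 10.8% in lethal and 49.6% in viable, FUS3 at 0% and 23.9%, SWN at 2.90% and 37.8%, DMS3 at 2.5% and 21.7%, and AGL28 at 5.17% and 41.0%. AGL23, AGL95, CLSY1, DML2, FIE, MET1, SUVH8 and SUVH9 made up the rest. It was lower in viable at AGL46, AGO4 and SUVH6 (26.5% to 0% of 154 calls). CG was higher in viable at 8 list genes and lower at 9, with the same counts adjusted over the list alone. Of all measured protein-coding genes, 6.60% had a CG region higher in viable and 7.16% one lower. The RdDM genes AGO4 (0% to 75.0%, 1909 bp beside the gene), AGO6 (0% to 58.8%), DCL3 (26.9% to 75.9%) and RDR2 (33.3% to 76.7%) were among the higher list genes, with FWA (2.13% to 50%), VIM5, LEC1 and DME. YUC10 (90% to 13.0%), DML3 (48.8% to 4.88%), ADM (39.3% to 2.63%), SDC, CLSY1, SWN, CMT2, SHB1 and KTF1 (80.9% to 34.2%) were lower. The regions of YUC10 and DML3 lay 1822 and 1274 bp beside the gene. CKX2 was the 1 list gene with lower CHG, 32.2% in lethal and 4.00% in viable, and NRPD1 the 1 with higher CHG. Outside the lists, CHH was higher in viable beside AAP3 (0% to 68.8% of 16 calls), NIP5;1, a boron channel gene (8.97% to 72.4%), and HA6 (0% to 57.9%), and lower beside CER3 (66.7% of 6 calls to 3.23%), DWF4 (69.2% to 12.7%) and MEE48 (57.0% to 0.658%). CG was lower at PUM25 and SMAP2, which share a region (100% to 0% of 25 calls), and MYR1, and higher beside EDA2, AGL83 and CYP705A6 (0% to 97.8%). CHG was lower beside chr31, SCRL11 and SDR1 and higher beside MYB109 (24.0% to 75.5%), RH8 and AtMT4b (12.5% to 53.2%). Counted per gene in the same way, 6 of these 18 calls passed with tests scaled to the estimated spread. They were those at PUM25 and SMAP2 (the same region), EDA2, CYP705A6, MEE48 and NIP5;1.

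With tests scaled to the estimated spread, 248 CHH regions were higher in viable than in lethal and 7 lower, 12 and 13 for CHG, and 214 and 312 for CG. Such a region was left at 0 of 13 list genes with higher and 0 of 3 with lower CHH, at 1 of 9 with lower CG (DML3) and 0 of 8 with higher CG, and at CKX2 and NRPD1 in CHG.

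Levels in viable lay between those of balanced and lethal at most regions of CHH and CHG loss in lethal. In the regions of CHH loss in lethal, viable averaged 12.9% ± 6.77 against 24.5% in balanced and 6.74% in lethal, which is 65.2% of the lethal difference, and 92.9% of regions lay in between. For CHG loss viable averaged 36.7% ± 13.2, or 65.4% of the lethal difference. For CG gains in lethal viable averaged 42.2% ± 23.1, or 52.6%. Regions picked in lethal overstate the lethal difference, so the reverse was computed: in regions of CHH loss in viable, lethal averaged 7.24% and showed 127% of the viable difference, and in those of CHG loss 93.7%. In these CHG losses lethal averaged 29.1% and viable 27.5%, and lethal lay between balanced and viable at 57.5% of regions. The order of lethal and viable in CHG thus depended on the cross in which regions were picked. In the CG gains of viable, lethal showed 53.8% of the viable difference, about the share that viable showed in those of lethal, so the CG values do not place viable between the others. Both differences subtract the same balanced calls, so error in balanced enters both and raises the shares at losses and gains in every context. How much of each share comes from this is not known, so the CG shares alone do not show a gain common to both crosses. CHH gains were little shared in either direction: those of lethal averaged 2.75% in balanced, 17.4% in lethal and 4.03% in viable, 8.78% of the lethal difference, and at those of viable lethal showed 8.97% of the viable difference.

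**Figure D4:**
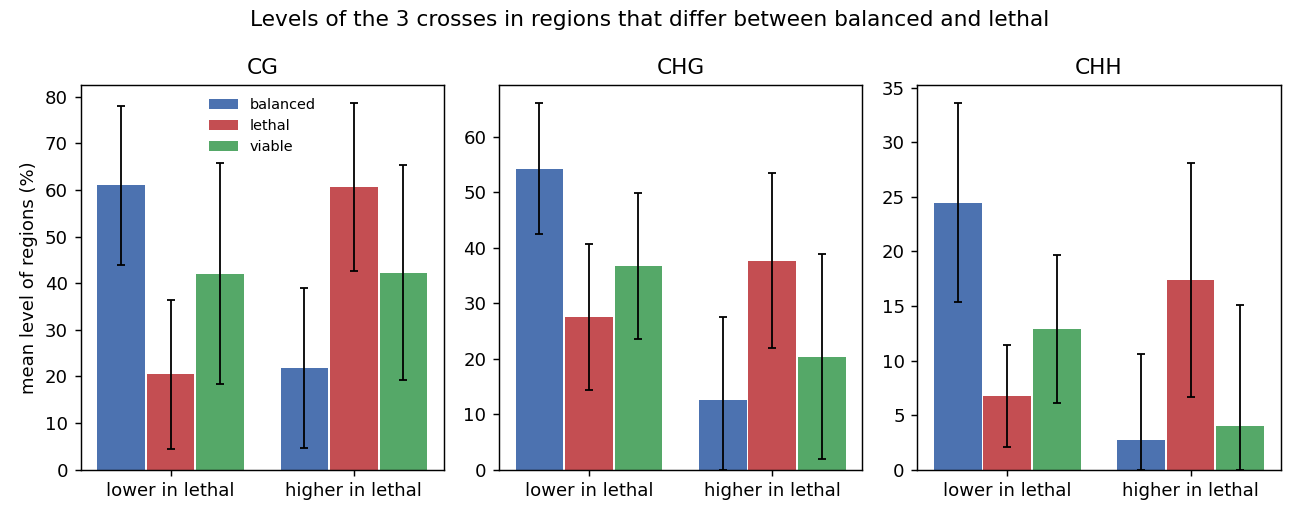
Mean level in percent (y axis) of the 3 crosses over regions lower or higher in lethal than in balanced (x axis) for CG, CHG and CHH; error bars are the SD over regions, drawn no lower than 0, not over samples. At CHH losses the bars stand at 24.5% in balanced, 6.74% in lethal and 12.9% in viable.

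Of the 11183 regions of CHH loss in lethal, 6899 (61.7%) shared at least 1 bp with a region of CHH loss in viable, as did 31.3% of CHG losses, 26.9% of CG gains and 23.8% of CG losses. Counted in windows, 23047 were CHH losses in both crosses, where independent lists would share 1177. Unchanged crosses simulated against the shared balanced calls gave 0 shared windows with counting error alone and 1499 with the estimated spread added. For CG gains the windows in both were 633, with 10.02 for independent lists and 61 in that simulation, and for CHG losses 2313, 55.3 and 2. Splitting the balanced libraries was not possible, so how much of the excess comes from the shared balanced calls is not known.

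CHH and CHG losses lay mostly away from protein-coding genes, and CG gains lay in them slightly more often than tested windows did. A loss could be called only where balanced held at least 10% CHH or 20% CHG. Balanced stood at 1.82% CHH and 3.34% CHG in gene-rich bins, against 10.4% and 30% in gene-poor ones. Tested windows were not matched for this level, so the shares of losses largely show where balanced carried such methylation. CG calls depended on the balanced level too, since a gain of 30 points needs room above it and a loss at least 30%. The CG shares and their p values below were not matched for this and so do not show a preference for or against genes. Protein-coding genes overlapped 15.6% of CHH and 12.8% of CHG losses in lethal, against 63.9% and 71.3% of tested windows, and in viable 15.2% and 14.3%. Pseudogenes overlapped 48.9% of CHG losses in lethal, and 47.3% of windows in these losses against 12.8% of tested ones. Gene-poor bins held 82.0% of CHH losses in lethal and 80.7% in viable, against 47.9% and 48.1% of tested windows. They also held 53.88% of CG gains in lethal and 57.55% in viable, against 47.58% and 47.74% of tested windows. CG regions that rose lay in protein-coding genes in 74.0% of cases in lethal and 75.2% in viable. The tests compared windows. Of windows in these regions 72.9% did in lethal, against 68.4% of tested windows (Fisher's exact test, p = 5.31e-05). In viable 74.4% did, against 67.6% (Fisher's exact test, p = 3.2e-11). CG regions that fell did so in 46.8% of cases in viable and 70.0% in lethal. Of their windows 44.6% did in viable, against 67.6% of tested windows (Fisher's exact test, p = 8.91e-51). In lethal 69.5% did, against 68.4% (Fisher's exact test, p = 0.615). Of the CHH gains in lethal, 60.7% lay in protein-coding genes. Of their windows 60.2% did, against 63.9% of tested windows (Fisher's exact test, p = 0.148). Pseudogenes overlapped 4.59% of windows in these gains, against 10.8% of tested ones (Fisher's exact test, p = 4.51e-05).

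Losses in different contexts often lay at the same places. CHG losses in lethal overlapped CHH losses in 61.9% of cases, against 7.89% for random placements, and in viable in 56.2% against 5.15%. CG losses in viable overlapped CHH losses in 38.4% against 5.61%, and in lethal in 19.1% against 8.19%. The random placements drew on all tested windows, whatever their level in balanced. Losses could be called only where balanced was methylated, so these shares do not show that losses coincide beyond the places of methylation. Between lethal and viable, 162 of the 1370 regions with lower CG in viable overlapped regions with higher CHH in viable, where the highest of 1000 random placements gave 45. These placements were not matched for level either. Lower CG needed at least 30% CG in lethal, and the regions of higher CHH averaged 31.4% CHH in balanced. This overlap thus does not show opposite changes of CG and CHH beyond the places of methylation.

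No fixed list differed from all measured genes after Benjamini-Hochberg adjustment over 162 tests (Fisher's exact test, two-sided). The smallest p belonged to the type I MADS-box list for CHH loss in lethal, with 52.6% of its members against 22.5% of all measured protein-coding genes (Fisher's exact test, p = 0.00401, adjusted p = 0.474). With regions inside the gene alone, 9 of its 19 members (47.4%) had CHH loss in lethal against 5.88% of all genes (Fisher's exact test, adjusted p = 7.21e-05) and 6 had it in viable (adjusted p = 0.0106). Within 500 bp the adjusted p was 0.0222 in lethal, so this call depended on the distance from the gene.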

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

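The location test of the CHH gains was chosen only after the result was seen. Lethal and viable moved in opposite directions from balanced in some regions, with all 3 pairs of crosses differing at an adjusted p below 0.01 but no minimum difference. At the differences required of the authors' regions, 0 CG windows were lower in lethal and higher in viable and 6 the reverse, 0 CHG windows moved in opposite directions, and 13 and 2 CHH windows did. Independent lists would share 3.122 and 4.894 such CG windows and 9.799 and 12.39 CHH windows. The counts 0 and 2 lay below these numbers, and 6 and 13 little above them. No such numbers are given for the region counts that follow, made without the minimum difference. CG was lower in lethal and higher in viable in 43 regions, of which 79.1% overlap a protein-coding gene, and higher in lethal and lower in viable in 59, of which 54.2% do. CHG was lower in lethal and higher in viable in 6 regions. CHH was lower in lethal and higher in viable in 22 regions, and higher in lethal and lower in viable in 13.

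Mitochondrial reads, which no comparison used, had a CG level of 11.17% in viable, against 6.833% in balanced and 7.394% in lethal. Chloroplast reads had a CHH level of 1.043% in lethal, against 0.6115% in balanced and 0.466% in viable, and made up 7.233% of all CHH calls in lethal against 4.172% in balanced.

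CHH was higher in lethal than in balanced at 336 regions, of which 3 passed with tests scaled to the estimated spread of the calls (that beside MEE48 did, that beside AGL46 did not), and the higher chloroplast level makes incomplete bisulfite conversion a candidate explanation. Unconverted fragments keep all their cytosines, and in windows of these regions CHG was higher in lethal by a mean of 6.31 percentage points ± 1.11 (95% half-width, 188 regions) and CG by 8.52 ± 1.37 (207 regions), against 15.0 for CHH. The CHG value lies between the values set for and against the explanation, so incomplete conversion and a gain in lethal endosperm cannot be told apart here. Of these regions 60.7% ± 5.22 overlap a protein-coding gene, while 15.6% of CHH losses do. Losses could be called only where balanced was methylated, whereas these gains averaged 2.75% in balanced. Of windows in the gains 60.2% overlap a protein-coding gene, near the 63.9% of tested windows (Fisher's exact test, p = 0.148). The shares thus cannot decide whether CHH was gained at the places where CHH regions otherwise lie, and that explanation stays open. A biological effect of paternal dosage stays open and untested.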

How the results depend on the processing

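The tests scaled to the estimated spread, the thinned viable calls and the subtracted chloroplast level were chosen only after the result was seen. No paired analysis was possible because the tables hold 1 pooled set of calls per cross. For the same reason the model across replicates, the replicate block and the analyses without a replicate were not run. Region counts stayed within 1.5 times when rebuilt with the minimum difference (18 of 18), with at least 6 shared cytosines (18 of 18) and with viable thinned (12 of 12), as did the percent of windows past both thresholds with the deposited p, 20 calls and windows that do not overlap (18 of 18 each). Depth limits the smaller changes, and the cause of the changes given next was not tested where the alternative's own stricter or looser criterion does not show it.

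Region counts are given in the order lethal lower and higher than balanced, viable lower and higher than balanced, viable lower and higher than lethal. A stricter difference gave 228, 621, 501, 719, 788 and 501 in CG, 1412, 5, 722, 7, 15 and 36 in CHG, and 7164, 129, 5244, 91, 192 and 2131 in CHH. No minimum difference gave 2053, 7596, 3198, 10944, 4990 and 4808 in CG, 8951, 536, 8095, 188, 280 and 505 in CHG, and 17968, 8171, 19845, 678, 9737 and 7686 in CHH, where viable lower than lethal then outnumbered viable higher. Tests scaled to the spread gave 41, 158, 129, 285, 312 and 214 in CG, 981, 3, 449, 1, 13 and 12 in CHG, and 1701, 3, 1701, 16, 7 and 248 in CHH. A stricter adjusted p moved 10 of 18 counts. In CG it gave 291 and 1020 regions lower and higher in lethal and 617 lower in viable than in balanced. In CHG it gave 1475 and 5 regions lower and higher in viable than in balanced and 21 and 56 lower and higher than in lethal. In CHH it gave 191 regions higher in lethal and 77 higher in viable than in balanced, and 284 lower in viable than in lethal.

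Differences in level follow in percentage points, in the order lethal minus balanced, viable minus balanced, viable minus lethal. The mean of window levels gave 1.33, 1.26 and -0.07 in CG, so that lethal minus balanced and viable minus lethal turned from -0.78 and 2.51. It gave -2.08, -1.98 and 0.102 in CHG, and -1.67, -1.33 and 0.336 in CHH. Windows in all 3 tables gave -0.74, 1.82 and 2.56 in CG, -2.95 and 1.60 for the last 2 in CHG, and -2.45 and -1.87 for the first 2 in CHH. Subtracting the chloroplast level gave -1.22, 1.86 and 3.09 in CG, -5.01, -2.86 and 2.14 in CHG, and -2.89, -1.74 and 1.16 in CHH. In gene-rich bins it turned viable minus lethal from -0.079 to 0.498 in CHH and from -0.09 to 0.485 in CHG, and lethal minus balanced from 0.27 to -0.173 in CG.

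With overlap of at least 50% of the shorter region, 3 instead of 5 CG regions higher in viable than in lethal shared a CHG region, and the other overlaps in the same direction stayed within 1.5 times, as did the 162 regions of lower CG and higher CHH in viable than in lethal (137). Within 500 bp of a protein-coding gene lay 63.49% of CG regions lower in viable than in balanced and 67.66% of those lower than in lethal, which turned from above to below the share of tested windows, while 16 of 18 shares kept their side. Of the gene list tests, 2 passed with regions inside the gene alone and 1 within 500 bp, against 0 within 2 kb.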

Other observations

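The interval of the median CHH level, its values outside genes, the thinning of the viable calls and the simulated power of the bound test were chosen only after the result was seen. The longest changed stretches carried losses of CHH methylation. The longest loss in lethal spanned 15300 bp of chromosome 4, from 4053501 to 4068800, where the level in the window of largest difference was 46.7% in balanced, 3.68% in lethal and 18.6% in viable. The longest loss in viable spanned 6700 bp of chromosome 2, from 4961001 to 4967700, with 56.3% in balanced, 3.64% in lethal and 10.7% in viable. The longest region with more CHH in viable than in lethal, 3100 bp of chromosome 3 from 14297501 to 14300600, stood at 57.9% in balanced, 4.17% in lethal and 54.4% in viable.

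In CG, a stretch of chromosome 5 from 16604101 to 16605400 stood at 5.39% in balanced, 78.0% in lethal and 42.1% in viable. A stretch of chromosome 1 from 19962901 to 19964300 stood at 60.8% in balanced, 63.0% in lethal and 1.85% in viable. The longest CHG loss in lethal, 2200 bp of chromosome 1 from 3329501 to 3331700, stood at 52.3% in balanced, 22.8% in lethal and 40.9% in viable.

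CG regions lower in viable than in lethal overlapped protein-coding genes in 52.8% of cases, against 75.9% of those higher in viable. Greater depth of the viable libraries was argued against as the cause, since after thinning 51.8% ± 2.76 of 1258 regions overlapped one. These regions may be places that carry CHH methylation in balanced, but over all of them the median balanced CHH level was 4.89% (bootstrap interval 4.15% to 5.88%), near the value set against this. In the 647 outside genes it was 14.7%, above the 10% set for it, and in the 274 outside genes that were higher in viable 2.68%, so the explanation stays open. An effect of the nrpd1 father stays open and was not tested apart from the cross.

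CG gains in both paternal excess crosses could follow from the higher share of Col genomes alone, with fixed parental methylation, which allows no change larger than the rise in the paternal share of the genome. All 888 windows called higher in lethal lay beyond it as measured, since calls need 30 points, and 11.5% did so by a one-sided test at an adjusted p of 0.01, which 169 of them would pass at their depth if each truly lay 25 points beyond. Fathers that differ in the methylation of their own alleles would allow up to 50 points between lethal and viable. Of 1493 windows called between them, 399 differed by more as measured and 1.47% by that test, which 28.5% would pass if each lay 25 points beyond. Neither explanation can be told apart from others here, since the test has little power at this depth and covers counting error only.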
